A study of Mus musculus with 8 samples.

How the data were processed

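Kidney RNA of C57BL/6 mice was measured in 8 libraries, 2 in each of the groups WT_DMSO, WT_FP, PKD_DMSO and PKD_FP, with groups and replicate numbers taken from the labels. Total RNA was extracted with TRIzol and sequenced by BGI from oligo(dT)-selected libraries, per the labels' protocols. The deposited values were FPKM, rounded to 2 decimals, with 20245 genes in each file. The file headers name no unit. FPKM was inferred from the deposited values: they were not whole numbers, their sums ranged from 486060 to 572823, and the sum of value times transcript length less 200 bp was near the same total in every library, as FPKM or RPKM would give. Whether reads or fragments were counted is not given in the sources used here. Bowtie2, DESeq2 and the build mm10 are named without version or role, per the submitters' processing notes, and the counting tool, annotation and gene lengths are not given in the sources used here. The number of reads per library is unknown, so no interval or floor from counts was computed.

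Comparisons, tests, named genes and gene lists were chosen before the data were examined. The planned test was a quasi-likelihood test of edgeR on counts, with limma on log2(value + 1) stated as the fallback for values that are not counts, and the fallback was used. From the deposited FPKM, log2(FPKM + 1) was computed. Genes with at least 1 FPKM in at least 2 libraries were kept, which left 14391. No further scaling was applied. One linear model with a mean for each of the 4 groups was fitted to all 8 libraries with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (trend and robust settings on). P-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The contrasts were PKD_DMSO vs WT_DMSO, PKD_FP vs PKD_DMSO, WT_FP vs WT_DMSO, PKD_FP vs WT_FP and the interaction of genotype and drug. With 2 libraries per group, a permutation test of a single value cannot give a two-sided p below 0.33. The low-value filter, the absence of further scaling and the trend setting were set after the values had been seen.

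Gene lists (44 fixed, 40 tested, of which 24 were pathway and 16 cell type lists) were tested with limma camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. The same lists were tested with the correlation estimated from the data and with fry, which asks whether the genes of a list move one way without comparing them with other genes. With an estimated correlation the test draws on only the residual degrees of freedom of 8 libraries in 4 groups, which leaves it little power. It called 0 lists in every contrast, so the lack of a call with it does not show that a list was unchanged. Members past the threshold were counted over all genes and adjusted over the list alone.

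Genes were named by a rule: 8 genes fixed in advance for P-TEFb and polycystins, and the 8 genes per direction with the largest log2 fold change among those past the threshold in each of the first 3 contrasts whose groups did not overlap. It also named 5 for the interaction, the 5 with the smallest p where none passed, and up to 4 members per list described. A pair of genes that the rule named is not reported here. Names of predicted genes, microRNAs and small nucleolar RNAs were skipped. The rule's minimum level was read as a mean log2(FPKM + 1) of 1, in place of log2 CPM. Snord68, and in the closing section Adipoq, Ucp1, Cfd, Ddx3y and Xist, were singled out after their values were seen. Symbols were matched to RefSeq for coordinates (GRCm38.p6, the assembly of mm10; 20154 of 20245 matched) and to GENCODE M21 for transcript length and GC content (19929 matched). Left out were 4 entries of 2 symbols that occur 2 times each, and 1 entry whose symbol is a dash, the latter after first results had been seen, which changed no count of calls.

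Gene tests were tested on simulated data built on the real means, with 100 genes changed per fold size in each of 5 data sets. Noise was drawn independently for each gene and library from the fitted spread. Recovery and false call rates, here and below, hold for that setting only. The real comparisons can differ in the number of changed genes and in correlation between genes or libraries. False calls made up 5.66% of calls for PKD_DMSO vs WT_DMSO, 5.51% for PKD_FP vs PKD_DMSO, 7.50% for WT_FP vs WT_DMSO, 6.10% for PKD_FP vs WT_FP and 7.57% for the interaction. In simulated data a list shifted by 0.5 on the log2 scale was recovered, and 1 of 39 unshifted lists was called. The simulated genes were independent, so that run does not test the list calls under correlation between genes.

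Alternatives named in advance were no low-value filter, replicate number as a block, only the groups compared, each library left out in turn, and for lists the estimated correlation and fry. Those added after the values had been seen were median-of-ratios scaling, quantile normalization, a pseudocount of 0.1, a stricter filter of 5 FPKM, a correction for transcript length and GC content (splines with 4 degrees of freedom). Also added were a block with the WT_DMSO numbers swapped, and leaving out 256 microRNA and small nucleolar RNA genes. A library left out leaves 1 library in its group, which is then assumed to vary like the other groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.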

Results

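Poly(A) RNA of whole kidneys from C57BL/6 mice was sequenced in 8 libraries, 2 in each of 4 groups. Wild-type (WT) kidneys and kidneys with autosomal dominant polycystic kidney disease (PKD) had been given vehicle (DMSO) or FP, which the series design gives as flavopiridol, an inhibitor of cyclin-dependent kinases including CDK9. CDK9 is the catalytic subunit of P-TEFb, the kinase complex that releases paused RNA polymerase II, and the study concerns its activation by cAMP and protein kinase A in the cystic kidney. The mutated gene, the dose and the age of the mice are not given in the sources used here, and the labels do not state whether replicates are separate animals, so the p-values measure only the spread between these samples. The values were FPKM, and their sum per library ranged from 486060 to 572823. Read depth is unknown, so no counting interval or detection floor can be given. Between 17861 and 18395 genes per library had a value above 0, and 12790 to 13813 reached 1 FPKM.

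The libraries separated first by genotype. The first principal component held 57.7% of the variance and ran from −53.60 to −28.59 in WT libraries and from 33.73 to 51.45 in PKD libraries. The second component held 20.1% and was positive in WT_DMSO replicate 1 (21.80), WT_FP replicate 2 (29.85), PKD_FP replicate 1 (5.88) and PKD_FP replicate 2 (37.34), and negative in the other libraries. Pearson correlations across genes, which are not independent replicates, were 0.96 to 0.97 within groups, 0.941 to 0.986 between the treatments of a genotype and 0.874 to 0.926 between genotypes.

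Comparing PKD with WT kidneys under vehicle asks what the disease changed without drug. Transcripts of tubule injury and of acute-phase proteins were among those with the largest increases. Lcn2, which encodes the injury marker NGAL (GRCm38 chromosome 2, 32384637 to 32387739), averaged 933 ± 272 FPKM (SD, n = 2) in PKD_DMSO against 7.75 ± 1.85 in WT_DMSO, a log2 fold change of 6.72 ± 0.32 (SE; limma with Benjamini-Hochberg, adjusted p = 0.000958). Havcr1, which encodes the proximal tubule injury marker KIM-1 (chromosome 11, 46739822 to 46779578), averaged 125 ± 24.4 against 0.265 ± 0.00707 FPKM, a log2 fold change of 6.63 ± 0.56 (limma, adjusted p = 0.00186). The matrix metalloproteinase gene Mmp7 (chromosome 9, 7692090 to 7699585) rose by 6.01 ± 0.44 and the metalloproteinase inhibitor gene Timp1 (chromosome X, 20870166 to 20874737) by 5.49 ± 0.44. Fgg, encoding the fibrinogen gamma chain (chromosome 3, 83007724 to 83015056), rose by 5.49 ± 0.53, from 2.12 ± 1.30 to 134 ± 20.8 FPKM. Complement C3 (chromosome 17, 57203967 to 57228136) rose by 5.43 ± 0.38, from 3.04 ± 0.255 to 183 ± 82.3 FPKM. Serpina10, which encodes an inhibitor of coagulation proteases (chromosome 12, 103616675 to 103631490), rose by 4.90 ± 0.26.

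Transcripts of the distal and proximal tubule were among those with the largest decreases. Pvalb, which encodes the calcium-binding protein parvalbumin (chromosome 15, 78191112 to 78206400), averaged 0.03 ± 0.0424 FPKM in PKD_DMSO against 35.3 ± 2.66 in WT_DMSO. Its log2 fold change of −5.14 ± 0.20 had the smallest adjusted p of the comparison (limma with Benjamini-Hochberg, 0.000656). For Pvalb and Havcr1, each near 0 FPKM in 1 group, the size of the fold depends on the 1 FPKM added before the logarithm. Egf, a growth factor gene of the distal nephron (chromosome 3, 129677574 to 129755322), changed by −4.85 ± 0.42, from 353 ± 60.7 to 11.9 ± 5.76 FPKM. Miox, encoding the proximal tubule enzyme myo-inositol oxygenase (chromosome 15, 89334473 to 89337007), changed by −4.35 ± 0.48. Kap, the androgen-regulated transcript of the proximal tubule (chromosome 6, 133849855 to 133853667), changed by −3.86 ± 0.38, from 26280 ± 597 to 1959 ± 1040 FPKM. Aspdh (chromosome 7, 44465435 to 44467751) changed by −3.80 ± 0.38. Nccrp1 (chromosome 7, 28543592 to 28547748) changed by −5.55 ± 0.82 and the amino acid transporter gene Slc7a13 (chromosome 4, 19818727 to 19842213) by −3.95 ± 0.64, and both calls ended without PKD_DMSO replicate 2, with −5.70 and −3.74. The organic ion transporter gene Slc22a28 (chromosome 19, 8061958 to 8131982) changed by −3.70 ± 0.88. Its call ended with replicate number as a block (−3.70), without WT_DMSO replicate 2 (−2.61) and without PKD_DMSO replicate 1 (−3.78) or replicate 2 (−3.61).

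**Figure D1:**
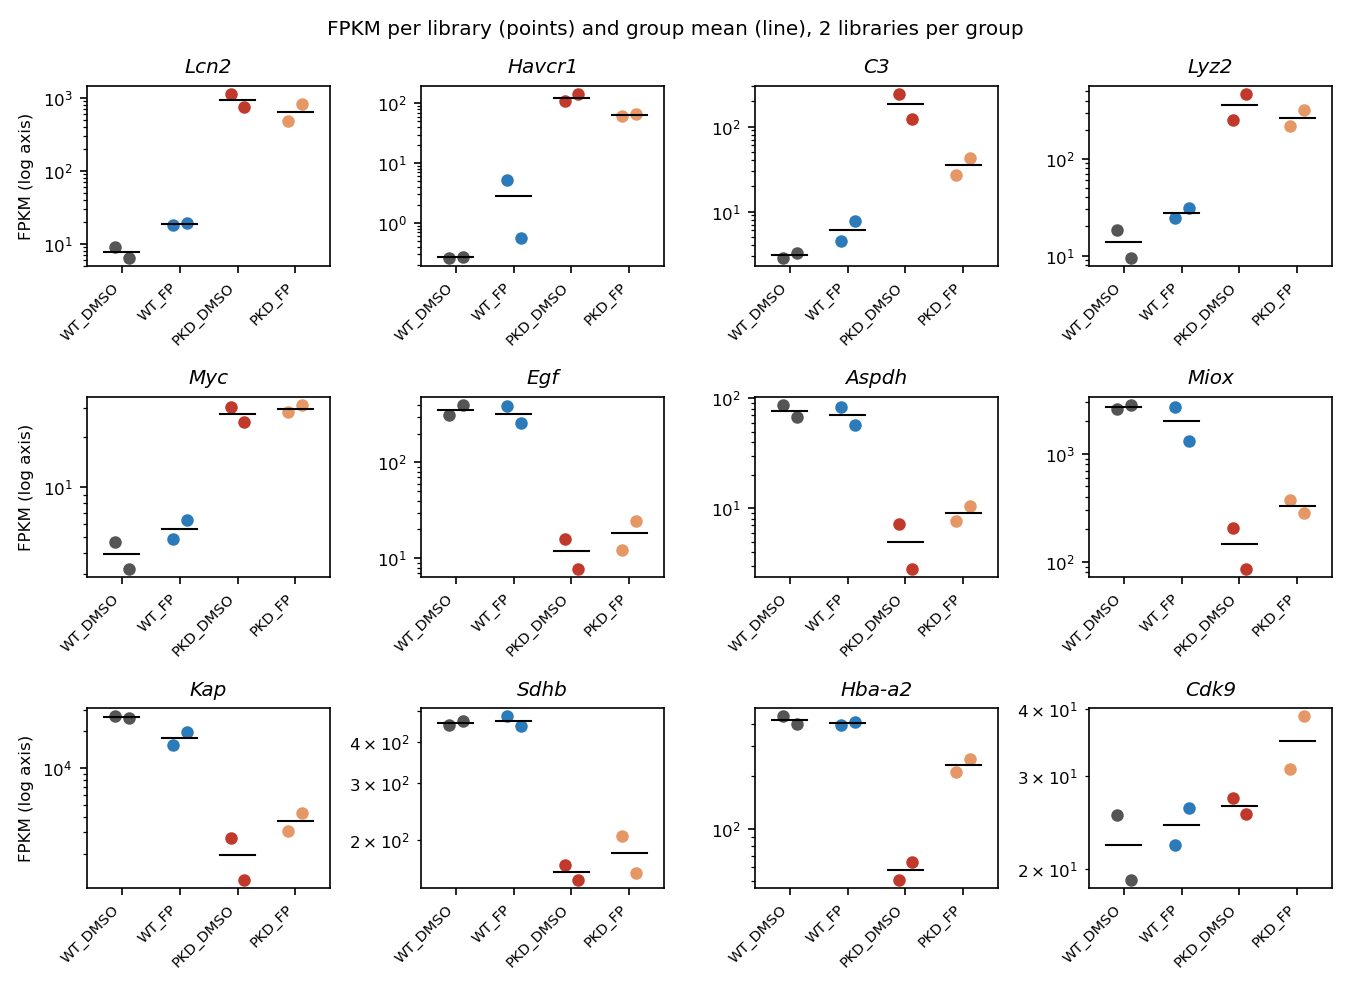
FPKM of 12 genes on a logarithmic axis in the 4 groups, with a point for each library and a line for the mean of each group. Lcn2 averaged 7.75 in WT_DMSO and 933 in PKD_DMSO, Egf 353 and 11.9, and Hba-a2 421 in WT_DMSO, 57.8 in PKD_DMSO and 232 in PKD_FP.

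Of 14391 genes tested by limma with Benjamini-Hochberg adjustment, 2130 were higher and 1082 lower in PKD_DMSO, of which 260 and 123 differed at least 4-fold. At an unadjusted p under 0.05 the counts were 3583 and 1890. In simulated data for this comparison the test recovered 33.4% of 2-fold and 90.0% of 4-fold changes over 14391 genes. The median log2 fold change of all genes was 0.12. The share of called genes that were higher, 66.3%, depended on the scaling. It was 53.9% after median-of-ratios scaling (1583 higher and 1353 lower), 52.8% after quantile normalization (1700 and 1522) and 53.4% after correction for transcript length and GC content (1476 and 1286). The counts fell without each of the 4 libraries compared, and less so without each FP library. Fewer libraries lower the power of the test, so the lower counts alone do not show reliance on a single library. Without PKD_DMSO replicate 2 they were 348 and 148, without PKD_DMSO replicate 1 1033 and 556, without WT_DMSO replicate 1 997 and 460, and without WT_DMSO replicate 2 877 and 619. In the fit of those 4 libraries alone 1408 genes were higher.

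Among the gene lists fixed in advance, tubule injury genes had 25 of 28 measured members higher and 0 lower over all genes, 28 adjusted over the list alone. Their median log2 fold change was 2.49 (limma camera with Benjamini-Hochberg, adjusted p = 1.77e-14; adjusted p = 0.22 with an estimated correlation). Spp1, encoding osteopontin, rose from 1308 ± 5.76 to 10490 ± 456 FPKM. Of 25 macrophage and myeloid markers, 24 were higher, 25 adjusted over the list alone, with a median of 2.44 (camera, adjusted p = 8.65e-12; adjusted p = 0.41 with an estimated correlation). The lysozyme gene Lyz2 rose by 4.60 ± 0.40, the Fc receptor gene Fcgr3 by 3.77 ± 0.34 and Trem2 by 3.59 ± 0.33. Immediate-early genes, whose transcripts depend on promoter-proximal pause release, had 20 of 25 members higher, 23 adjusted over the list alone, and a median of 1.63 (camera, adjusted p = 7.41e-11; adjusted p = 0.38 with an estimated correlation). Socs3 rose by 3.90 ± 0.25, Atf3 by 2.98 ± 0.28 and Myc by 2.53 ± 0.21. Complement and acute-phase genes had 12 of 20 higher, 14 adjusted over the list alone, and a median of 2.72 (camera, adjusted p = 1.01e-07; adjusted p = 0.22 with an estimated correlation), with the fibrinogen gene Fgb at 3.40 ± 0.27 and C4b at 2.68 ± 0.23.

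Extracellular matrix genes had 20 of 34 members higher, 26 adjusted over the list alone, and a median of 1.67 (limma camera with Benjamini-Hochberg, adjusted p = 2.28e-07; adjusted p = 0.81 with an estimated correlation). The collagen gene Col12a1 rose by 4.54 ± 0.49 and the thrombospondin gene Thbs1 by 2.84 ± 0.35. Among chemokines and cytokines 14 of 27 were higher and 1 lower, 21 and 2 adjusted over the list alone, with a median of 1.95 (camera, adjusted p = 9.58e-07; adjusted p = 0.35 with an estimated correlation). The monocyte attractant gene Ccl2 rose by 2.89 ± 0.23, and Il34, a ligand of the macrophage growth factor receptor, by 3.42 ± 0.20. Targets of the Hippo effector YAP had 11 of 17 higher, 12 adjusted over the list alone, and a median of 1.16 (camera, adjusted p = 5.26e-06; adjusted p = 0.35 with an estimated correlation), with Ankrd1 at 4.55 ± 0.41 and Cyr61 at 3.26 ± 0.39. Of 23 targets of p53, 9 were higher, 11 adjusted over the list alone, with a median of 0.60 (camera, adjusted p = 0.00209; adjusted p = 0.41 with an estimated correlation). Cdkn1a, encoding the cell cycle inhibitor p21, rose by 3.16 ± 0.33 and Gdf15 by 3.25 ± 0.23. Ribosomal protein genes had 11 of 57 higher, 10 adjusted over the list alone, and a median of 0.34 (camera, adjusted p = 0.0115; adjusted p = 0.82 with an estimated correlation), and the call ended after median-of-ratios scaling (0.20) and without WT_DMSO replicate 2 (0.23). Mitosis genes had 4 of 32 higher, 1 adjusted over the list alone, and a median of 0.33 (camera, adjusted p = 0.0216; adjusted p = 0.82 with an estimated correlation). That call ended after quantile normalization (0.13), with a stricter filter (0.33), after length and GC correction (0.20), without WT_DMSO replicate 1 (0.38) and without PKD_DMSO replicate 2 (0.26).

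Lists of mitochondrial metabolism and of several tubule segments were called lower, while glycolysis (median 0.16) and principal cells (−0.56) were not called. In whole-kidney RNA a change in the mix of cells and a change within cells cannot be told apart for these lists. Of 46 oxidative phosphorylation genes, 38 fell and 0 rose over all genes, 40 adjusted over the list alone, with a median of −1.13 (limma camera with Benjamini-Hochberg, adjusted p = 3.34e-24; adjusted p = 0.22 with an estimated correlation). The complex I gene Ndufa8 changed by −1.44 ± 0.16, the cytochrome oxidase gene Cox7b by −1.46 ± 0.15 and the succinate dehydrogenase gene Sdhb, also a member of the tricarboxylic acid cycle list, by −1.53 ± 0.18. The tricarboxylic acid cycle had 9 of 26 members lower, 14 adjusted over the list alone, and a median of −0.68 (camera, adjusted p = 1.86e-08; adjusted p = 0.63 with an estimated correlation). Fatty acid oxidation had 8 of 32 lower, 11 adjusted over the list alone, and a median of −0.42 (camera, adjusted p = 0.000125; adjusted p = 0.82 with an estimated correlation), and the call ended without WT_DMSO replicate 2 (−0.18). Proximal tubule markers had 12 of 30 lower, or 19 lower and 2 higher adjusted over the list alone, with a median of −1.55 (camera, adjusted p = 1.43e-08; adjusted p = 0.63 with an estimated correlation). The phosphate transporter gene Slc34a3 changed by −3.58 ± 0.34 and the glucose transporter gene Slc5a2 by −2.85 ± 0.38. Thick ascending limb and distal convoluted tubule markers had 10 of 20 lower, 11 adjusted over the list alone, and a median of −0.96 (camera, adjusted p = 6.04e-07; adjusted p = 0.22 with an estimated correlation).

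Markers of intercalated cells, the acid-base cells of the collecting duct, had 9 of 16 members lower, 11 adjusted over the list alone, and a median of −1.27 (limma camera with Benjamini-Hochberg, adjusted p = 2.28e-07; adjusted p = 0.38 with an estimated correlation). The anion exchanger gene Slc4a1, also a member of the erythroid list, changed by −3.29 ± 0.31 and the proton pump gene Atp6v1c2 by −2.21 ± 0.24. Erythroid genes had 6 of 8 lower, 6 adjusted over the list alone, and a median of −2.62 (camera, adjusted p = 2.13e-07; adjusted p = 0.22 with an estimated correlation). The alpha globin gene Hba-a2 averaged 57.8 ± 9.52 FPKM against 421 ± 30.4, and the values of single globin genes are uncertain because near-identical copies can share reads. Endothelial markers had 1 of 20 lower, 0 adjusted over the list alone, and a median of −0.69 (camera, adjusted p = 0.0011; adjusted p = 0.82 with an estimated correlation), and the call ended without PKD_DMSO replicate 1 (−0.08). Of the 18 lists called, 0 were called with an estimated correlation and 11 by fry. For each of the 18 the estimated correlation gave the highest adjusted p of its alternatives. That test has little power with 2 libraries per group, so it does not decide whether these lists changed.

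**Figure D2:**
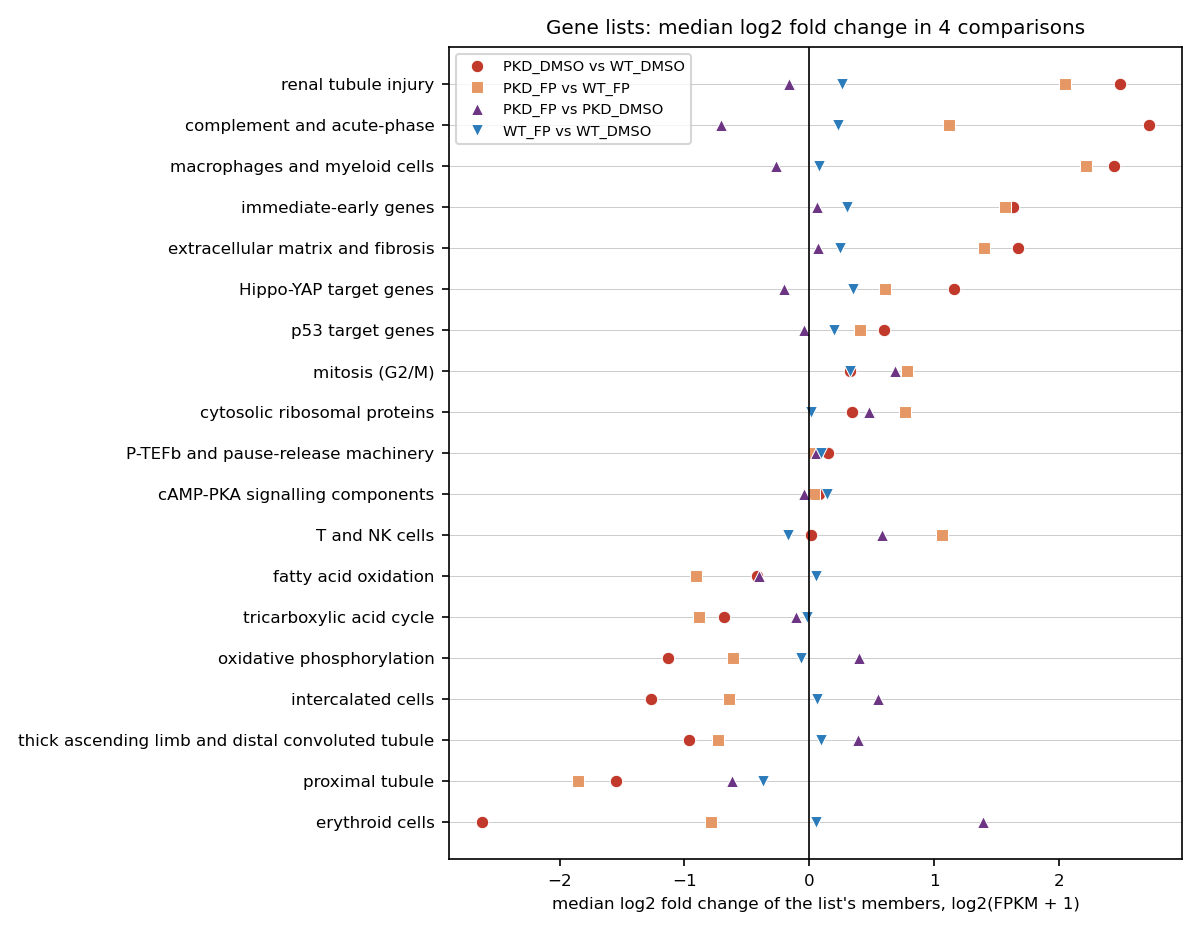
Median log2 fold change of the members of 19 gene lists, with a marker for each of 4 comparisons and a line at no change. Oxidative phosphorylation stood at −1.13 in PKD_DMSO vs WT_DMSO, −0.61 in PKD_FP vs WT_FP and 0.40 in PKD_FP vs PKD_DMSO. For the last value a drug effect and a trend with transcript length cannot be told apart. Tubule injury stood at 2.49, 2.05 and −0.16 in the same comparisons.

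Transcripts of P-TEFb and its regulators were compared because the study concerns activation of this complex. Transcript levels do not measure the activity of the complex, so they do not test its activation. None of the genes fixed for naming and given here passed the threshold between PKD_DMSO and WT_DMSO. Cdk9 (chromosome 2, 32705782 to 32712784) averaged 26.3 ± 1.34 FPKM against 22.2 ± 4.34, a log2 fold change of 0.25 with a 95% interval of −0.21 to 0.70 (limma with Benjamini-Hochberg, adjusted p = 0.382). The interval excluded a 2-fold change in either direction, as it did for Pkd2, Ccnt2, Hexim1 and Pkd1, and included one for Ccnt1 and Larp7. The cyclin T genes Ccnt1 (chromosome 15, 98538690 to 98567736) and Ccnt2 (chromosome 1, 127774164 to 127804837) stood at 0.10 and 0.09. Hexim1, which encodes the inhibitor that holds P-TEFb inactive (chromosome 11, 103116325 to 103119725), stood at −0.22. Larp7, encoding the protein that stabilizes 7SK RNA (chromosome 3, 127536714 to 127553349), stood at −0.60 with an interval of −1.12 to −0.09 (limma, adjusted p = 0.0884). It passed after median-of-ratios scaling (−0.74), quantile normalization (−0.74) and length and GC correction (−0.66), and its adjusted p ranged from 0.0264 to 0.309 over the alternatives. The polycystin genes Pkd1 (chromosome 17, 24548689 to 24596514) and Pkd2 (chromosome 5, 104453982 to 104505819) stood at 0.08 (−0.59 to 0.76) and 0.42 (0.10 to 0.74), and FPKM over a whole gene does not test the loss of an exon.

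The list of P-TEFb and pause-release genes had 3 of 31 members higher and 1 lower, 2 and 1 adjusted over the list alone. Its median was 0.15 and became −0.01 after quantile normalization and −0.02 after length and GC correction (limma camera with Benjamini-Hochberg, adjusted p = 0.944; adjusted p = 0.99 with an estimated correlation). The super elongation complex genes Aff4 and Aff1 rose by 0.86 ± 0.17 and 0.73 ± 0.17, Eaf1 rose by 0.54 ± 0.15, and the elongation factor gene Ell3 changed by −1.18 ± 0.19. Without PKD_DMSO replicate 2 all of these 4 calls ended, with 0.68, 0.72, 0.49 and −1.003. Without WT_DMSO replicate 1 the calls of Aff4 (0.77), Aff1 (0.69) and Eaf1 (0.45) also ended. So did those of Aff1 and Eaf1 without WT_DMSO replicate 2 (0.76 and 0.63) and without PKD_DMSO replicate 1 (0.73 and 0.58), and that of Eaf1 without any of the 4 FP libraries (0.54). After length and GC correction Aff4 (0.53), Aff1 (0.40) and Eaf1 (0.25) did not pass. Eaf1 also did not pass after median-of-ratios scaling (0.41) or quantile normalization (0.37), or without the low-value filter, with the block or in the fit of the groups compared (0.54 in each). Components of cAMP and protein kinase A signalling had 4 of 32 higher and 1 lower, 3 and 1 adjusted over the list alone. Their median was 0.08 and became −0.04 after median-of-ratios scaling, −0.07 after quantile normalization and −0.14 after length and GC correction (camera, adjusted p = 0.923; adjusted p = 0.99 with an estimated correlation). Transcripts that respond to cAMP had 5 of 21 higher and 1 lower, 6 and 1 adjusted over the list alone, and a median of 0.52 (camera, adjusted p = 0.112; 0.58 and past the threshold without the low-value filter). Of these, Fos rose by 2.39 ± 0.23, Junb by 2.39 ± 0.28 and Nr4a1 by 1.63 ± 0.21, and Fos, Junb and Nr4a1 are also immediate-early genes.

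**Figure D3:**
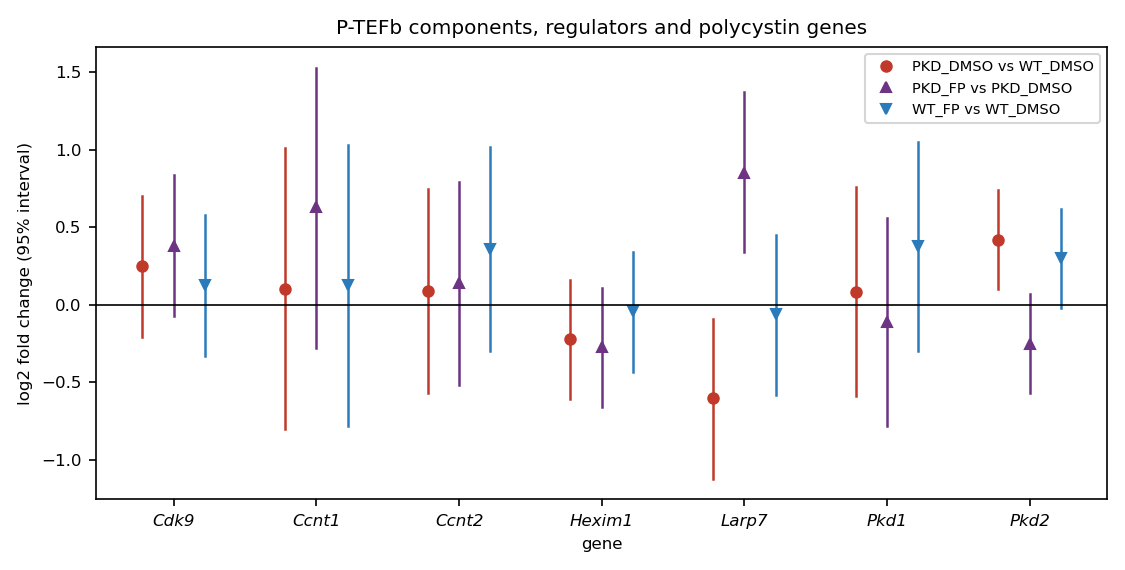
Log2 fold changes of Cdk9, Ccnt1, Ccnt2, Hexim1, Larp7, Pkd1 and Pkd2 in 3 comparisons, with points for estimates and bars for 95% intervals from limma. Cdk9 stood at 0.25 in PKD_DMSO vs WT_DMSO, 0.38 in PKD_FP vs PKD_DMSO and 0.13 in WT_FP vs WT_DMSO, and none of these genes passed an adjusted p of 0.05 in any of the 3 comparisons.

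Comparing PKD_FP with PKD_DMSO asks what the drug changed in diseased kidneys. The beta globin gene Hbb-bt (chromosome 7, 103812524 to 103813923) was the only gene past the threshold in the upward direction, with 63.4 ± 5.15 FPKM (SD, n = 2) in PKD_FP against 7.57 ± 2.08, a log2 fold change of 2.93 ± 0.19 (limma with Benjamini-Hochberg, adjusted p = 0.0225). The alpha globin gene Hba-a2 followed at 1.99 ± 0.18 without passing (adjusted p = 0.052), and near-identical globin copies make single globin values uncertain. In the downward direction the only call was the small nucleolar RNA Snord68 (chromosome 8, 123103058 to 123103105), at 4.55 ± 0.113 FPKM in PKD_DMSO and listed at 0 in the other 3 groups, so no fold is given. It was singled out after its values were seen, and its length of under 200 bases makes its FPKM from a poly(A) library uncertain. At an unadjusted p under 0.05 limma gave 1488 genes higher and 1316 lower, with 720 expected by chance over both directions. In simulated data for this comparison the test recovered 33.4% of 2-fold and 90.0% of 4-fold changes over 14391 genes. The Hbb-bt call ended in the fit of the groups compared (2.93), after length and GC correction (2.64) and in each of the 8 fits without 1 library (2.68 to 3.18). Its adjusted p ranged from 0.0147 to 0.276 over its alternatives.

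Gene lists were tested in the same comparison, and the calls with the preset correlation were not kept with an estimated one. Mitosis genes had all 32 members at positive values, 0 past the threshold over all genes and 21 adjusted over the list alone, with a median of 0.69 (limma camera with Benjamini-Hochberg, adjusted p = 6.86e-13; adjusted p = 0.65 with an estimated correlation). The kinetochore genes Ndc80 and Nuf2 stood at 1.13 ± 0.20 and 1.02 ± 0.18 and the mitotic kinase gene Plk1 at 0.87 ± 0.16. DNA replication genes had a median of 0.39 with 0 of 29 past either threshold (camera, adjusted p = 2.41e-05; adjusted p = 0.97 with an estimated correlation), a call that ended without PKD_FP replicate 1 (0.23). Markers of T and NK cells had a median of 0.58, with 0 of 10 past over all genes and 4 higher adjusted over the list alone (camera, adjusted p = 0.000651; adjusted p = 0.34 with an estimated correlation). The T cell receptor component gene Cd3g averaged 4.19 ± 0.467 against 0.635 ± 0.177 FPKM (1.67 ± 0.22) without passing (limma adjusted p = 0.124). The call of the T and NK list ended without PKD_FP replicate 1 (list median 0.42). Erythroid genes had 1 of 8 higher, 6 adjusted over the list alone, and a median of 1.39 (camera, adjusted p = 4.34e-06; adjusted p = 0.34 with an estimated correlation).

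Complement and acute-phase genes had a lower median, −0.71, with 0 of 20 past over all genes and 4 lower adjusted over the list alone (limma camera with Benjamini-Hochberg, adjusted p = 9.23e-05; adjusted p = 0.61 with an estimated correlation). Fgg averaged 18.4 ± 1.29 FPKM against 134 ± 20.8 (−2.79 ± 0.53) and C3 35.2 ± 11.3 against 183 ± 82.3 (−2.30 ± 0.38), and each had a limma adjusted p of 0.124. Proximal tubule markers had a median of −0.62, with 0 of 30 past over all genes and 2 lower adjusted over the list alone (camera, adjusted p = 0.0025; adjusted p = 0.97 with an estimated correlation). The amino acid transporter gene Slc6a19 stood at −2.58 ± 0.39, and the list's call ended without PKD_DMSO replicate 1 (−0.30) and without PKD_FP replicate 2 (−0.16). Fatty acid oxidation had a median of −0.40 with 0 of 32 past either threshold (camera, adjusted p = 0.000122; adjusted p = 0.97 with an estimated correlation), and the same libraries ended its call (−0.20 and −0.16). Cholesterol synthesis also had a median of −0.40, with 0 of 23 past either threshold (camera, adjusted p = 9.23e-05; adjusted p = 0.97 with an estimated correlation), a call that ended without PKD_FP replicate 2 (−0.25). NRF2 and glutathione genes had a median of −0.40 with 2 of 24 lower adjusted over the list alone and 0 over all genes (camera, adjusted p = 0.000314; adjusted p = 0.76 with an estimated correlation). Gsta1, whose value is uncertain because close copies can share reads, stood at −1.61 ± 0.26.

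Oxidative phosphorylation genes had a median of 0.40 under FP, with 0 of 46 past over all genes and 21 higher adjusted over the list alone (limma camera with Benjamini-Hochberg, adjusted p = 8.1e-07; adjusted p = 0.97 with an estimated correlation). Ribosomal protein genes had a median of 0.48 with 0 of 57 past either threshold (camera, adjusted p = 3.6e-10; adjusted p = 0.97 with an estimated correlation), and the call ended after quantile normalization (0.10). Both lists hold short transcripts. Across 13361 protein-coding genes with a known transcript length, fold changes in this comparison correlated with length (Spearman −0.34), with medians of 0.47 below 1 kb and −0.20 above 8 kb. Intercalated cell markers had a median of 0.55, with 0 of 16 past over all genes and 5 higher adjusted over the list alone (camera, adjusted p = 0.00222; adjusted p = 0.97 with an estimated correlation), and the call ended without PKD_DMSO replicate 2 (0.30). Endothelial markers had a median of 0.60 with 0 of 20 past either threshold (camera, adjusted p = 0.0196; adjusted p = 0.97 with an estimated correlation), which became −0.03 without PKD_DMSO replicate 1 and was not called without PKD_FP replicate 2 (0.38). Of the 13 lists called, 0 were called with an estimated correlation, which gave the highest adjusted p of each list's alternatives, and 3 were called by fry.

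The lists closest to the drug's target did not pass in PKD_FP vs PKD_DMSO. RNA levels of these genes do not measure whether the drug inhibited the kinase. P-TEFb and pause-release genes had a median of 0.05 with 0 of 31 past either threshold (limma camera with Benjamini-Hochberg, adjusted p = 0.955), and immediate-early genes had a median of 0.06 with 0 of 25 past either threshold (camera, adjusted p = 0.912). Tubule injury genes had a median of −0.16 and macrophage markers of −0.27, each with a camera adjusted p of 0.206. Both passed after length and GC correction (−0.21 and −0.40) and without PKD_FP replicate 2 (−0.27 and −0.38), injury genes also after quantile normalization (−0.26), and macrophage markers also without PKD_DMSO replicate 1 (−0.76). Cdk9 stood at 0.38 (−0.07 to 0.84), Hexim1 at −0.27 (−0.66 to 0.11) and Larp7 at 0.85 (0.34 to 1.37; limma adjusted p = 0.135).

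Comparing WT_FP with WT_DMSO asks what the drug changed in healthy kidneys. Limma with Benjamini-Hochberg called 0 genes in either direction, and 131 were higher and 52 lower at an unadjusted p under 0.05, fewer than the 720 expected by chance over both directions. WT_FP replicate 1 correlated at 0.986 with WT_DMSO replicate 2, and WT_FP replicate 2 at 0.979 with WT_DMSO replicate 1. The 2 WT_FP libraries correlated at 0.964. Such spread within groups can hide drug differences, so the 0 calls do not show that the drug left WT kidneys unchanged. The recovery rates given below assume independent libraries. The smallest adjusted p of the comparison, 0.277, belonged to a microRNA gene. Among genes that the naming rule does not skip, the smallest unadjusted p-values belonged to Gsta1 (1.77 ± 0.26; limma adjusted p = 0.65), the chemokine gene Ccl5 (−1.32 ± 0.23), Zfp868 (1.35 ± 0.25), Methig1 (1.45 ± 0.33) and Tmem221 (−0.97 ± 0.22). In simulated data for this comparison the test recovered 33.4% of 2-fold and 90.0% of 4-fold changes over 14391 genes. Mitosis genes had all 32 members at positive values and a median of 0.33, with 0 past over all genes and 0 adjusted over the list alone (limma camera with Benjamini-Hochberg, adjusted p = 3.58e-09; adjusted p = 0.81 with an estimated correlation). The proliferation marker gene Mki67 averaged 5.73 ± 0.474 against 3.88 ± 0.247 FPKM (0.46 ± 0.17), and the list's call ended without WT_FP replicate 1 (0.21). Adipocyte markers had a median of 2.09 with 0 of 12 past either threshold (camera, adjusted p = 3.88e-06; adjusted p = 0.81 with an estimated correlation), which rested on WT_FP replicate 2 and was 0.14 and not called without it.

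Camera called 8 lists higher and 11 lower in WT_FP vs WT_DMSO, 0 of them with an estimated correlation (smallest adjusted p = 0.48) and 0 by fry, whose adjusted p of 0.98 was the highest of the alternatives for each list. Lists with small higher medians were YAP targets (0.35), immediate-early genes (0.30), tubule injury genes (0.26), cAMP-responsive transcripts (0.22), p53 targets (0.20) and growth factors (0.18). The call of the YAP list ended without WT_DMSO replicate 2 (0.17), that of immediate-early genes also without WT_FP replicate 2 (0.05 in each fit), and those of the other 4 lists without WT_DMSO replicate 1 (0.50, 0.35, 0.33 and 0.36) and without WT_FP replicate 2 (0.03, −0.08, 0.12 and 0.12). Without WT_DMSO replicate 2 the calls of tubule injury genes (0.09), cAMP-responsive transcripts (0.15) and growth factors (0.08) ended. Without WT_FP replicate 1 or PKD_FP replicate 2 that of growth factors ended (0.30 and 0.17). Length and GC correction also ended the growth factor call (0.06). It kept the calls of p53 targets (0.10) and cAMP-responsive transcripts (0.12) at lower medians. Proximal tubule markers had a median of −0.37 that became −0.03 without WT_DMSO replicate 2, with no call, and 0.13 without WT_FP replicate 2. Markers of T and NK cells had a median of −0.17 (camera, adjusted p = 0.000192; adjusted p = 0.48 with an estimated correlation), and genes of the unfolded protein and integrated stress response of −0.06, a call that ended without WT_DMSO replicate 2 (−0.03) and without WT_FP replicate 1 (−0.05). The other 8 lists called lower had medians within 0.08 of 0, and for ribosomal, chemokine and interferon genes the median was above 0 while the test, which compares a list with all other genes, gave lower. None of these 8 calls was kept in all of the alternatives, and quantile normalization turned the test direction of oxidative phosphorylation (−0.003), the tricarboxylic acid cycle (0.04), NRF2 (−0.005) and ribosomal protein genes (0.09).

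None of the calls of those 8 small shifts in WT kidneys was kept in every fit without 1 library. Fold changes in this comparison also followed transcript length (Spearman 0.24 across protein-coding genes). With all libraries, length and GC correction ended the calls of chemokine (0.01), interferon (−0.03) and tricarboxylic acid cycle genes (−0.08). It also ended those of cholesterol synthesis (−0.12), NRF2 (−0.11) and ribosomal protein genes (−0.01). Before the correction these calls were near the threshold (camera, adjusted p from 0.0451 to 0.0499). The medians of the tricarboxylic acid cycle (−0.022), cholesterol synthesis (−0.028) and NRF2 genes (−0.049) had been closer to no change. The end of these calls therefore does not show that the shifts came from transcript length. The calls of oxidative phosphorylation (−0.10) and heat shock genes (−0.14) were kept after that correction. Without WT_DMSO replicate 2 the calls of oxidative phosphorylation (−0.08), cholesterol synthesis (0.16), heat shock (−0.06), NRF2 (−0.004) and chemokine genes (−0.18) ended, and the tricarboxylic acid cycle was called higher (0.23). Without WT_FP replicate 2 oxidative phosphorylation (−0.04), the tricarboxylic acid cycle (0.12), cholesterol synthesis (0.01), NRF2 (−0.003) and chemokine genes (0.03) did not pass. Without WT_DMSO replicate 1 chemokine (0.12) and ribosomal protein genes (0.12) did not pass and interferon genes were called higher (0.48), and without WT_FP replicate 1 interferon (0.23), heat shock (0.13) and ribosomal protein genes (0.09) did not pass. Without PKD_FP replicate 1 or 2 the calls of chemokine (0.05), interferon (0.01) and tricarboxylic acid cycle genes (−0.02) ended.

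Whether the drug effect differed between genotypes was tested as an interaction, which limma with Benjamini-Hochberg called for 0 of 14391 genes, with 640 positive and 976 negative at an unadjusted p under 0.05. In simulated data for this test 2.2% of 2-fold and 66.2% of 4-fold differences were recovered over 14391 genes. Among genes that the naming rule does not skip, Hbb-bt (2.54 ± 0.28) and Gsta1 (−3.38 ± 0.37) had an adjusted p of 0.239, and Hba-a2 (2.05 ± 0.25), the glycerol acyltransferase gene Gpam (−2.43 ± 0.32) and the lipid droplet gene Plin4 (−2.87 ± 0.39) followed. Cdk9 stood at 0.26 with an interval of −0.39 to 0.90. Camera called 7 lists with a positive and 7 with a negative interaction, 0 of them with an estimated correlation (smallest adjusted p = 0.14) and 2 by fry, T and NK cells and erythroid genes (adjusted p = 0.013 each). T and NK markers had a median interaction of 0.86 and erythroid genes of 1.25. Mitosis genes had a median interaction of 0.33 (camera, adjusted p = 3.35e-06; adjusted p = 0.82 with an estimated correlation).

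Under FP the disease contrast stayed large. In PKD_FP vs WT_FP Lcn2 was higher by 4.99 ± 0.32 (limma with Benjamini-Hochberg, adjusted p = 0.00305), Spp1 by 2.94 ± 0.22 and Myc by 2.22 ± 0.21, while Pvalb changed by −4.26 ± 0.20, Egf by −4.09 ± 0.42 and Kap by −2.27 ± 0.38. Limma called 1254 genes higher and 753 lower, of which 163 and 101 differed at least 4-fold, and 2723 and 1797 at an unadjusted p under 0.05. Injury genes had 25 of 28 members higher, 27 adjusted over the list alone, and a median of 2.05 (camera, adjusted p = 1.78e-15; adjusted p = 0.25 with an estimated correlation). Proximal tubule markers had 15 of 30 lower, 23 adjusted over the list alone, and a median of −1.85 (camera, adjusted p = 1.46e-13; adjusted p = 0.35 with an estimated correlation). Mitosis genes had 17 of 32 higher, 22 adjusted over the list alone, and a median of 0.78 (camera, adjusted p = 2.23e-09; adjusted p = 0.35 with an estimated correlation). T and NK markers had 7 of 10 higher, 7 adjusted over the list alone, and a median of 1.06 (camera, adjusted p = 0.000281; adjusted p = 0.25 with an estimated correlation). Of the 24 lists called in this comparison, 0 were called with an estimated correlation and 19 by fry, and its lists and single genes were not run under the other alternatives. The counts were 650 and 437 with replicate number as a block, 640 and 363 in the fit of the groups compared. They were 131 and 56 without PKD_FP replicate 2, 155 and 80 without WT_FP replicate 1, 204 and 99 without PKD_FP replicate 1. They were 647 and 467 without WT_FP replicate 2, 736 and 435 without PKD_DMSO replicate 1 and 735 and 435 without PKD_DMSO replicate 2. In simulated data for this comparison the test recovered 32.4% of 2-fold and 90.8% of 4-fold changes over 14391 genes.

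The disease contrasts in vehicle and under FP share no libraries, and their fold changes correlated across genes with r = 0.749. Of the 2130 genes higher in PKD_DMSO, 873 were also called higher under FP, where independent lists would share 186. Of the 1082 lower genes 448 were also called lower, where independent lists would share 56.6, and 1 gene was called in opposite directions. Both sets of calls rest on the same spread per gene, estimated from all 8 libraries. The numbers for independent lists are therefore no chance level for these overlaps. Among the genes called in vehicle the median disease change was 1.01 in vehicle and 0.67 under FP for those higher, and −1.11 and −0.75 for those lower, and selecting the genes in the vehicle contrast favours larger values there. The drug contrasts of PKD and WT kidneys correlated with r = 0.046. Snord68 was the only gene higher in the disease and lower with the drug, and Hbb-bt the only gene lower in the disease and higher with the drug, where independent lists would share 0.15 and 0.075. Those contrasts share the PKD_DMSO libraries with opposite sign, so some opposition arises by chance. The covariance of their fold changes across genes was −0.148, against −0.0442 (−0.0491 to −0.0413) in 100 simulations of unchanged groups with shared controls, a difference of −0.104. The correlation, −0.382 against −0.498 simulated (−0.534 to −0.47), and the share of disease-called genes with the opposite sign under the drug, 75.2% against 83.1% (81.3 to 84.8), showed less opposition than the simulations. The simulated groups held no disease difference, and a real one adds spread that weakens both measures, so they set no bound on opposition in either direction. With a different PKD_DMSO library in each contrast, computed after these values were seen, the covariance was −0.14 (r = −0.333) with replicate 1 in the disease contrast. It was −0.0693 (r = −0.154) with replicate 2 there. Fold changes of these contrasts followed transcript length with opposite signs, at Spearman 0.23 for PKD_DMSO vs WT_DMSO and −0.34 for PKD_FP vs PKD_DMSO. The simulations held no length trend, and the split does not remove a trend that both PKD_DMSO libraries share. These covariances therefore cannot tell a length trend from an effect of the drug.

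**Figure D4:**
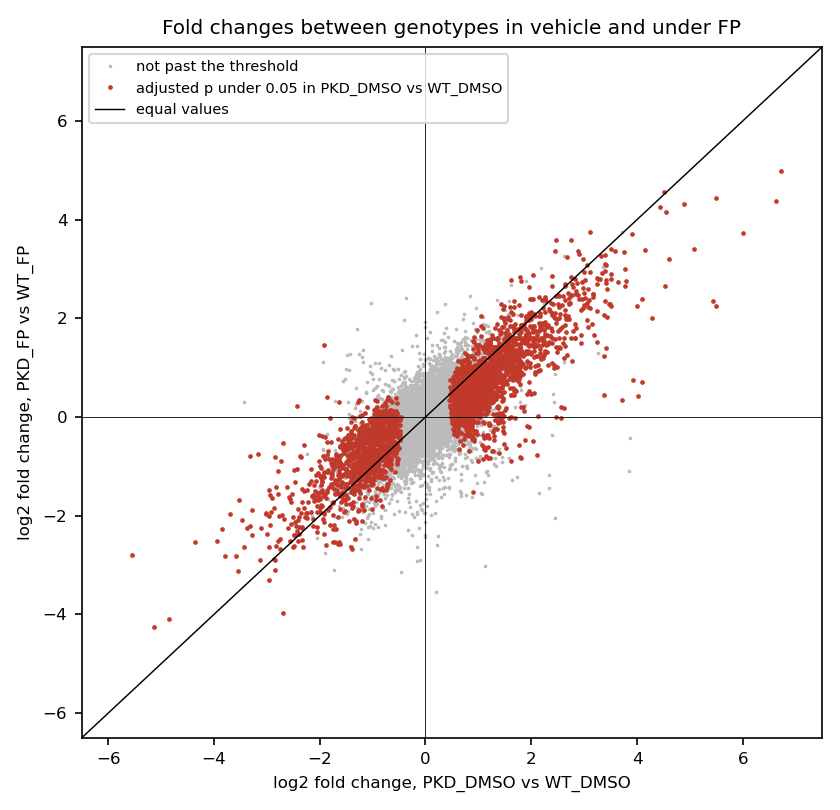
Log2 fold change of each gene in PKD_DMSO vs WT_DMSO (x axis) and PKD_FP vs WT_FP (y axis), with a line of equal values and genes past an adjusted p of 0.05 in PKD_DMSO vs WT_DMSO in red. The contrasts share no libraries and correlated with r = 0.749 across genes.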

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

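The tests of transcript length, blood and fat tissue were chosen only after the results were seen, and the rule of the length test was extended after its first outcome, which moved oxidative phosphorylation under FP from explained by length to undecided. For 14 lists limma camera with Benjamini-Hochberg called the interaction, a drug effect that differed between PKD and WT kidneys, and for none of them was it called with an estimated correlation.

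Oxidative phosphorylation and ribosomal protein genes, both lists of short transcripts, had median interactions of 0.50 (−0.07 in WT to 0.40 in PKD kidneys; camera, adjusted p = 2.95e-11) and 0.49 (0.01 to 0.48; camera, adjusted p = 1.35e-11), each with adjusted p = 0.82 with an estimated correlation. The fold changes of 13361 protein-coding genes followed length (Spearman −0.41 for the interaction), and replicates of PKD_DMSO differed along length too (−0.28). Length alone is argued against for oxidative phosphorylation in PKD_DMSO vs WT_DMSO by a percentile of 0 among 10000 random lists matched on length (−1.13 against −0.42 to 0.08), and by a narrow margin that ignores correlation between genes for ribosomal protein genes in PKD_FP vs PKD_DMSO (percentile 98.9; 0.48 against 0.20 to 0.47), whose median fell to 0.21 after length and GC correction with the call kept. For oxidative phosphorylation in PKD_FP vs PKD_DMSO the percentile was 86 (0.40 against 0.16 to 0.46) and the median fell to 0.19 after that correction with the call kept, so a drug effect and a length trend between libraries cannot be told apart. Length stays open as a part of the ribosomal shift, and a biological effect of the drug on both lists stays open and untested.

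Erythroid genes had a median interaction of 1.25 (camera, adjusted p = 4.88e-07; adjusted p = 0.14 with an estimated correlation), from 0.05 in WT to 1.39 in PKD kidneys; all 8 members reached 1 FPKM in WT_DMSO and 1 is also in another list. Summed alpha globin was 1207.8 and 1205.8 FPKM in WT_DMSO, 1076.6 and 1098.9 in WT_FP, 118.2 and 175.7 in PKD_DMSO, and 647.2 and 632.6 in PKD_FP. A length trend is argued against, since only 0.82% of 731 other genes under 1 kb had a higher fold change than Hba-a2 in PKD_FP vs PKD_DMSO. Different amounts of blood in the kidneys may account for part of it, since Alas2, which encodes the erythroid heme synthesis enzyme, moved with the globins and its ratio to alpha globin changed by at most 0.26 of the globin change on the log2 scale. That ratio changed by 0.65 in PKD_DMSO vs WT_DMSO and −0.55 in PKD_FP vs PKD_DMSO, and the beta to alpha globin ratio by 0.55 and −0.42. A difference in the amount of blood alone would leave both ratios unchanged. Alas2 is itself erythroid, so it cannot tell the amount of blood from a change in its transcripts. Whether such a difference in blood came from the handling of the kidneys, the disease or the drug was not tested.

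Adipocyte markers had a median interaction of −2.60 (camera, adjusted p = 0.00293; adjusted p = 0.82 with an estimated correlation), from 2.09 in WT to −0.65 in PKD kidneys. The WT value came from WT_FP replicate 2, whose median over 12 members exceeded WT_DMSO by 4.11 against 0.28 in WT_FP replicate 1, a share of 0.07, and without WT_FP replicate 2 the WT value was 0.14. Of the 12 members 5 reached 1 FPKM in WT_DMSO and 1 is also in another list. In that library Adipoq stood at 47.3, Ucp1 at 99.4 and Cfd at 230.3 FPKM. Fat tissue around the kidney in that sample is a candidate explanation, and an effect of the drug on fat in that sample stays open and untested.

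T and NK cell markers had a median interaction of 0.86 (camera, adjusted p = 4.09e-06; adjusted p = 0.14 with an estimated correlation), from −0.17 in WT to 0.58 in PKD kidneys. Intercalated cell markers had 0.51 (camera, adjusted p = 0.0059; 0.82 estimated), from 0.06 to 0.55, mitosis genes 0.33 (camera, adjusted p = 3.35e-06; 0.82 estimated), from 0.33 to 0.69, and DNA replication genes 0.18 (camera, adjusted p = 0.00205; 0.82 estimated), from 0.19 to 0.39. The interaction was negative for complement and acute-phase genes at −0.62 (camera, adjusted p = 0.000282; 0.71 estimated), from 0.23 to −0.71, and for cholesterol synthesis at −0.48 (camera, adjusted p = 0.0114; 0.90 estimated), from −0.03 to −0.40. YAP targets had −0.47 (camera, adjusted p = 0.034; 0.82 estimated), from 0.35 to −0.20, and tubule injury genes −0.43 (camera, adjusted p = 0.0205; 0.82 estimated), from 0.26 to −0.16. NRF2 and glutathione genes had −0.42 (camera, adjusted p = 0.034; 0.82 estimated), from −0.05 to −0.40, and fatty acid oxidation −0.38 (camera, adjusted p = 0.00205; 0.90 estimated), from 0.05 to −0.40. Lists of the interaction were not run under the other alternatives.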

How the results depend on the processing

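Median-of-ratios scaling, quantile normalization, the pseudocount of 0.1, the stricter filter, the length and GC correction, the swapped block and leaving out small RNAs were chosen only after the results were seen. Of 139 calls of named genes, 139 were kept with a pseudocount of 0.1, 132 after median-of-ratios scaling, 128 after quantile normalization, 127 after length and GC correction, 125 with the block, 129 without the filter, 128 with only the groups compared and 133 of 134 with the stricter filter. Leaving out 1 library kept between 66 (without PKD_DMSO replicate 2) and 134 (without WT_FP replicate 2), and none was reversed in any of these. A gene or list that was not called and changed sign without being called is counted as unchanged. Without the filter PKD_FP vs PKD_DMSO had 3 genes higher and 2 lower, WT_FP vs WT_DMSO 1 and 2, the interaction 7, and 2 genes were higher in disease and lower with the drug. With only the groups compared the counts were 1408 higher for PKD_DMSO vs WT_DMSO, 0 and 0 for PKD_FP vs PKD_DMSO, and 640 and 363 for PKD_FP vs WT_FP, where fewer samples set the spread. With replicate number as a block they were 650 and 437 for PKD_FP vs WT_FP, and with the WT_DMSO numbers swapped 3258 and 1821 for PKD_DMSO vs WT_DMSO, 12 and 17 for PKD_FP vs PKD_DMSO, 2184 and 1498 for PKD_FP vs WT_FP, and overlaps of 11 and 8. The differences between replicates correlated across genes from −0.515 to 0.485 between groups, so the numbers do not pair the samples. Values of −0.515 (WT_DMSO and WT_FP) and 0.485 (WT_FP and PKD_FP) show that replicates of several groups differed along shared genes. The model counts such variation as spread between replicates, and its source was not tested. The swap follows the negative correlations of WT_DMSO with the other groups, so a gain of calls was built into it and is no evidence for them. The block, the pseudocount of 0.1, the stricter filter and leaving out small RNAs each gave 0 genes lower in PKD_FP vs PKD_DMSO and an overlap of 0 for higher in disease and lower with the drug. Length and GC correction gave 0 genes higher and an overlap of 0 for the other direction. Of 18, 13 and 19 lists called in PKD_DMSO vs WT_DMSO, PKD_FP vs PKD_DMSO and WT_FP vs WT_DMSO, the estimated correlation called 0, 0 and 0 and fry 11, 3 and 0, and in WT_FP vs WT_DMSO the stricter filter called 10 and length and GC correction 12. Without 1 library PKD_DMSO vs WT_DMSO ranged from 348 to 1889 higher and 148 to 999 lower, PKD_FP vs WT_FP from 131 to 1155 and 56 to 705. The counts of PKD_FP vs PKD_DMSO, WT_FP vs WT_DMSO, the interaction and both overlaps ranged from 0 to 0, and lists called from 18 to 20, 12 to 19 and 11 to 21. Reversed in WT_FP vs WT_DMSO by the direction of the test were ribosomal protein genes with fry (0.012) and quantile normalization (0.092), and with quantile normalization oxidative phosphorylation (−0.003), the tricarboxylic acid cycle (0.042) and NRF2 genes (−0.005). Without WT_DMSO replicate 2 the tricarboxylic acid cycle (0.225), NRF2 (−0.004), extracellular matrix (−0.236), fatty acid oxidation (0.295), cholesterol synthesis (0.16) and proximal tubule (−0.034) reversed. Without WT_FP replicate 2 the same was so for the tricarboxylic acid cycle (0.116), fatty acid oxidation (0.19), cholesterol synthesis (0.014), proximal tubule (0.129), cAMP-responsive transcripts (−0.082) and papilla and urothelium (−0.457), without WT_DMSO replicate 1 for interferon genes (0.477), and without WT_FP replicate 1 for interferon (0.228) and heat shock genes (0.13). Over the fits without 1 library these lists ranged from −0.266 to 0.225 (tricarboxylic acid cycle), −0.144 to −0.003 (NRF2), −0.391 to 0.477 (interferon), −0.236 to 0.744 (extracellular matrix), and −0.193 to 0.295 (fatty acid oxidation). They ranged from −0.241 to 0.16 (cholesterol synthesis), −0.916 to 0.129 (proximal tubule), −0.174 to 0.13 (heat shock), −0.082 to 0.53 (cAMP-responsive) and −0.457 to 1.31 (papilla and urothelium). In PKD_FP vs PKD_DMSO endothelium reversed without PKD_DMSO replicate 1 (−0.034; range −0.034 to 1.169) and extracellular matrix without PKD_DMSO replicate 2 (0.439; range −0.476 to 0.439). Apart from the smaller sample and gene numbers these alternatives bring, the cause was not tested. The planned DESeq2 size factors in edgeR and the DESeq2 Wald test were not run, since they need counts. Depth is unknown, so what it limits could not be assessed.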

Other observations

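The tests of the mitosis list were chosen only after its values were seen. Growth factor and receptor genes moved both ways in PKD_DMSO vs WT_DMSO, with 6 of 27 higher and 3 lower over all genes, 8 and 3 adjusted over the list alone (limma camera with Benjamini-Hochberg, adjusted p = 0.49). Hbegf, an EGF receptor ligand gene, rose by 1.99 ± 0.23 and Pdgfb by 1.80 ± 0.25, against the fall of Egf (−4.85 ± 0.42). Fibroblast markers had 5 of 20 higher and 1 lower, 5 and 1 adjusted over the list alone (camera, adjusted p = 0.112), with Thy1 at 3.12 ± 0.40 and Mfap5 at 3.08 ± 0.37. The list passed after median-of-ratios scaling (0.50), length and GC correction (0.43), without WT_DMSO replicate 1 (1.15) and without PKD_DMSO replicate 1 (1.18). Smooth muscle markers had 3 of 11 higher, 5 adjusted over the list alone (camera, adjusted p = 0.112), and passed without WT_DMSO replicate 1 (1.30) and without PKD_DMSO replicate 1 (1.02). NRF2 and glutathione genes had 6 of 24 higher, 6 adjusted over the list alone (camera, adjusted p = 0.491; 0.37 and past the threshold after quantile normalization), with Gsta1, whose value is uncertain because close copies can share reads, at 3.72 ± 0.26. Papilla and urothelium markers had 2 of 12 higher, 2 adjusted over the list alone (camera, adjusted p = 0.214), with the keratin genes Krt14 at 3.78 and Krt17 at 3.64.

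Podocyte markers had 4 of 16 lower, or 5 lower and 4 higher adjusted over the list alone, and a median of −0.62 in PKD_DMSO vs WT_DMSO (limma camera with Benjamini-Hochberg, adjusted p = 0.0734), which passed with the stricter filter (−0.70) and without PKD_DMSO replicate 2 (−1.09). Principal cell markers had 1 of 18 higher, the sialyltransferase gene St6gal1 at 1.63 ± 0.14, and a median of −0.56 (camera, adjusted p = 0.137). DNA replication genes had 4 of 29 higher and 2 lower, 4 and 2 adjusted over the list alone, and a median of 0.51 (camera, adjusted p = 0.0561). The list passed without the low-value filter (0.50), with a pseudocount of 0.1 (0.55), after length and GC correction (0.37), without WT_DMSO replicate 2 (0.56), without PKD_DMSO replicate 1 (0.64) and without PKD_FP replicate 1 or 2 (0.51 in each). Of 5 B cell markers 0 passed in limma, and the list passed without the low-value filter (−0.15). Interferon response genes (median 0.10), glycolysis (0.16), cholesterol synthesis (0.49; past the threshold without WT_DMSO replicate 2, 0.45) and the unfolded protein and integrated stress response (0.36; past the threshold after quantile normalization, 0.31, and without WT_DMSO replicate 2, 0.47) were not called. Heat shock genes (−0.15), imprinted genes (0.49), neutrophils (1.03; past the threshold without PKD_DMSO replicate 2, 1.88), adipocytes (1.36), T and NK cells (0.01) and adrenal cortex (−0.32) were not called either. Papilla and urothelium markers differed within FP groups, with list medians relative to the mean of all libraries of −1.05 and 0.78 in WT_FP replicates 1 and 2 and −0.46 and 1.38 in PKD_FP, against −0.19 and −0.70 in WT_DMSO and 0.13 and 0.22 in PKD_DMSO. Principal cell markers stood at −0.22 and 0.34 in WT_FP and, in the opposite order, 0.18 and 0.08 in PKD_FP. The Y-linked gene Ddx3y ranged from 13.7 to 21.8 FPKM and Xist from 0.02 to 0.13 over the 8 libraries.

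Mitosis genes stood higher in the FP libraries of both genotypes, with list medians relative to the mean of all libraries of −0.43 and −0.46 in WT_DMSO, −0.05 and −0.23 in WT_FP, −0.18 and 0.03 in PKD_DMSO, and 0.75 and 0.56 in PKD_FP. A hypothesis is that FP raised these transcripts in both genotypes. Chance order of the libraries was not excluded. Of 40 lists, 2 had all FP libraries on the same side of the DMSO libraries in both genotypes. These were mitosis and DNA replication, both cell cycle lists and both higher with FP. By chance 2.2 lists are expected, with an upper 95% bound of 5 if the lists are independent. An effect confined to these cell cycle lists could not exceed that bound, so the count cannot decide the order of the mitosis list itself. Of the 8 fits without a single library, 7 kept the call in both genotypes, and without WT_FP replicate 1 the WT call ended (0.21). In WT kidneys the rise may therefore rest on a single library, WT_FP replicate 1, and chance order of the libraries stays open for both genotypes.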
